A study of Homo sapiens with 6 samples.

How the data were processed

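RNA from K562 cells was extracted with magnetic beads and made into mRNA sequencing libraries, per the labels' protocols. The 6 libraries were grouped by the genotype in their labels into 3 SF3B1-WT and 3 SF3B1-K700E libraries. The authors deposited TPM values per gene (reads divided by gene length, scaled to 1000000 per library) in a table per genotype. Per the file headers, the WT table has the layout of featureCounts output with the exons and length of each gene, and its column names end in the form that the aligner STAR gives its sorted files. The submitters' processing notes name cutadapt 2.10, TopHat2 2.1, featureCounts 2.0.1, DESeq2 and the build GRCh37 (hg19), so the aligner of the WT libraries is not settled by these sources. The aligner and the counting settings behind the K700E table, strand included, are not given in the sources used here, and a difference in aligner between the tables would coincide with genotype.

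Both tables listed the same 62111 gene IDs in the same order, and 58604 of them (94.4%) were matched to a symbol in a table of gene names. Gene types and GC content came from GENCODE annotation and transcripts of a later build and were joined by gene ID only. All coordinates are those of the deposited table on GRCh37. Every column summed to 1000000. TPM multiplied by the deposited gene length gave whole multiples of a single step per library for 100% of genes above 0 in all 6 libraries, within a tolerance of 0.01. Each library was therefore scaled alone, with the same gene lengths in both tables, and this was the condition set for testing across the tables. The recovered totals of 104642332 to 136588117 reads per library count read ends, since genes with 2 reads outnumbered genes with 1 (2994 against 1139 in WT replicate 1). A read end was worth between 17.3 and 23.0 TPM multiplied by bases of gene length, depending on the library. Counting error is therefore small for long or abundant genes, where the spread between libraries sets the precision. It is not small for short genes near 1 TPM or where the mean of a group lies well under 1 TPM.

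Genes with a mean of at least 1 TPM over the 6 libraries (15493) were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, using empirical Bayes moderation with a trend on mean level, genotype as the only term, and Benjamini-Hochberg adjustment at 0.05. The test was two-sided. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated, adjusted over 31 lists with at least 3 tested members each. The exact permutation p of a single gene cannot go below 0.1 with 3 libraries against 3. Design, lists, alternatives and the rule for named genes were written before the data were examined. The rule took SF3B1, then the 12 largest log2 changes in each direction among called genes with non-overlapping groups and a gene name that is not a clone or pseudogene name, then up to 4 members of each list by smallest adjusted p. Some genes that the rule takes are not reported here.

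The procedure was tested on simulated data drawn from the library means and spread, in 5 runs of the K700E against WT comparison with a median of 15464 genes tested. It recovered 37.1% of genes changed 2-fold and 75.8% of those changed 4-fold, with 43 false calls among 606 (7.1%). A shifted list was found in 5 of 5 runs and 0 of 150 unchanged lists were called. The simulation drew libraries independently, which WT replicate 3 may not be. It also drew genes independently, so it could not show false list calls that come from correlated genes. In the deposited data, other groupings of the 6 libraries, 3 against 3, called 4 to 16 lists.

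The alternatives were pseudocounts of 0.1 and 5, no filter or a filter at 5 TPM, median-ratio and TMM scaling, limma without the trend, leaving out each library, the replicate number as a block, protein-coding nuclear genes alone, a 1.5-fold minimum, and the estimated list correlation. Added after the data were seen were a loess correction on GC content (97.7% of tested genes had a value), limma-voom on the recovered reads of genes with a mean of at least 10, and both of these without WT replicate 3. The GC correction subtracted the whole fitted curve, so it also centred each library on the mean over all libraries. The tables were joined and the figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Splice junctions and isoforms were not analysed here.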

Results

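RNA was measured by sequencing in K562 cells, a human line from the blast crisis of chronic myeloid leukaemia with erythroid and megakaryocytic features. SF3B1 is the largest subunit of the SF3b complex, the part of the U2 snRNP that binds the branch point of an intron, and K700E is its most common substitution in blood cancers. There were 3 libraries from cells with wild-type SF3B1 (WT) and 3 from cells with SF3B1-K700E. The deposited values were TPM per gene for 62111 genes, with the WT libraries in one table and the K700E libraries in another. Whole reads recovered from the TPM values came to 104.6, 133.6 and 136.6 (in units of 1000000) for WT replicates 1, 2 and 3, and to 111.6, 123.0 and 126.5 for K700E replicates 1, 2 and 3. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these libraries. Values per gene hold no splice junctions and no bases, so neither splice site use nor the substitution itself was measured here.

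The comparison asked which genes differed in level between K562 cells with and without the substitution, and the series title directs it to splicing and to cell cycle checkpoint genes. SF3B1 itself (ENSG00000115524, GRCh37 chromosome 2, 198254508 to 198299803, minus strand) stood at 119 ± 22.6 TPM in WT and 138 ± 21.5 TPM in K700E (SD, n = 3 each). By library it was 144, 98.9 and 115 TPM in WT and 160, 136 and 118 TPM in K700E. The log2 difference of 0.22 (SE 0.18) had a limma adjusted p of 0.602, within the spread between libraries.

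In K700E cells 178 genes were higher and 36 lower than in WT among 15493 genes tested, at a limma adjusted p under 0.05. On the log2(TPM + 1) scale the largest rise among them was in PAEP, which encodes the secreted protein glycodelin, from 6.448 ± 1.204 to 194 ± 169 TPM (SD, n = 3 each). IL13RA2, a decoy receptor for interleukin 13, rose from 0.860 ± 0.167 to 27.3 ± 15.4 TPM, and EPHB6, an Eph receptor without kinase activity, from 8.66 ± 4.32 to 82.1 ± 27.3 TPM. TFPI2, a serine protease inhibitor, rose from 0.612 ± 0.134 to 13.6 ± 3.89 TPM, and FLT1, a VEGF receptor, from 0.746 ± 0.332 to 12.8 ± 6.50 TPM. Of those that fell, S100P, a calcium-binding protein, went from 335 ± 134 to 90.6 ± 17.2 TPM, PHGDH, the first enzyme of serine synthesis, from 404 ± 106 to 135 ± 46.1 TPM, and the long non-coding RNA LINC01419 from 46.8 ± 16.3 to 5.55 ± 3.18 TPM.

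The other genes named by the rule showed the same kind of change, most of them from a low level. GNG12, ACTL8, LINC00564 and the GABA receptor subunit gene GABRQ rose, with log2 differences of 2.84, 2.78, 2.67 and 2.58. PAGE5, LINC01300, the metallothionein gene MT1G, the integrin gene ITGA4, NEBL, ARHGDIG and ONECUT3 fell, with log2 differences of -2.35, -2.08, -1.87, -1.62, -1.54, -1.49 and -1.48. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes, and 70 of the 178 higher genes had a WT mean under 1 TPM. All 214 had library values that did not overlap between the groups. Over all tested genes 3721 (24.0%) did not overlap, where chance gives 10% for 6 independent libraries. Without WT replicate 3, which lay between the other two WT libraries in most genes, 4074 (26.3%) did not overlap, where chance gives 20%. Protein-coding genes made up 111 of the higher and 26 of the lower genes, and 20 of the 214 were annotated pseudogenes, whose reads can be shared with their parent genes.

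The count of calls rested on single libraries. Without WT replicate 3 limma called 0 genes, with 1462 at an unadjusted p under 0.05 against 2563 with all 6 libraries, and limma-voom on the recovered reads also called 0 without it (2415 unadjusted). The counts of higher and lower genes were 144 and 38 without WT replicate 1, 98 and 27 without WT replicate 2, 82 and 16 without K700E replicate 1, 78 and 6 without K700E replicate 2, and 109 and 20 without K700E replicate 3. The median gene had a log2 difference of 0.13, and TMM scaling, which moved it to -0.01, gave 110 higher and 41 lower genes (72.8% higher, against 83.2%). All 214 genes kept their direction in each of these limma fits to TPM, but this is no evidence that the calls are stable. Their values did not overlap between the groups, so leaving out 1 library could not reverse the direction. The shift of the median gene under TMM scaling was also smaller than the planned minimum fold change, which all 214 met. Changes of gene lists are given below relative to the median gene.

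**Figure D1:**
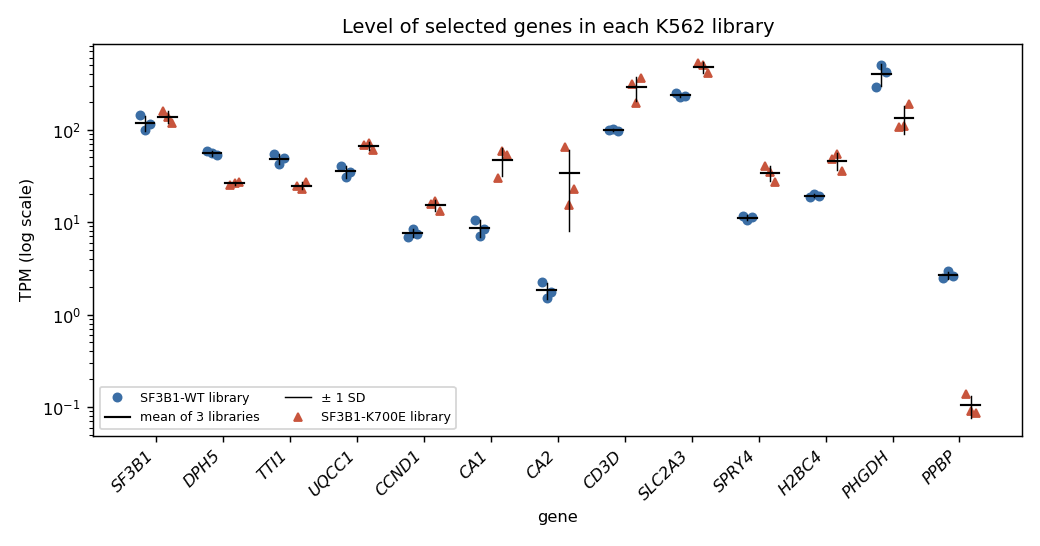
TPM on a log axis for 13 genes in each of the 6 K562 libraries (circles, WT; triangles, K700E), with the mean of 3 libraries as a horizontal line and 1 SD as a vertical line. SF3B1 overlaps between the groups (means 119 and 138 TPM), whereas DPH5 is lower in K700E (55.7 and 26.3 TPM) and CD3D higher (99.8 and 289 TPM).

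Of 25 genes reported to use cryptic 3' splice sites in SF3B1-mutant cells, 3 fell, 1 rose and 21 did not pass the test. The list test (camera with a preset correlation) placed them lower than other genes at an adjusted p of 0.0038, and the adjusted p was 0.765 with an estimated correlation. Their median log2 difference was 0.03, or -0.10 relative to all genes, and 9 of the 25 lay above the median gene. DPH5, an enzyme of diphthamide synthesis, fell from 55.7 ± 3.32 to 26.3 ± 1.08 TPM (SD, n = 3 each; log2 difference -1.05, SE 0.12, limma adjusted p 0.016), and TTI1, a partner of the kinases of the TOR and ATM family, from 48.6 ± 5.66 to 24.8 ± 2.05 TPM. UQCC1, an assembly factor of respiratory complex III, rose from 35.5 ± 5.16 to 66.7 ± 6.18 TPM. Leaving out 1 library, the limma adjusted p of DPH5 ran from 0.0283 to 0.114, over 0.05 without WT replicate 3 or K700E replicate 2, and that of UQCC1 from 0.0327 without WT replicate 1 to 0.231. Without WT replicate 3 the log2 difference was -1.09 for DPH5 and 0.894 for UQCC1, against -1.05 and 0.897 with all libraries. Adjusted over the list alone, 6 fell and 1 rose.

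The machinery that reads 3' splice sites and the nonsense-mediated decay factors had no member past the threshold. Of 24 U2 snRNP and branch point genes, SUGP1, the partner whose contact with SF3B1 the substitution disturbs, stood at 28.95 ± 4.63 TPM in WT and 43.2 ± 4.03 TPM in K700E (limma adjusted p 0.148), and SF3B3 at 80.9 ± 3.00 and 109 ± 4.35 TPM (0.132). The list test gave an adjusted p of 0.227. Among 17 decay factors NBAS had the smallest limma adjusted p, 0.137, at 119 ± 11.4 TPM in WT and 83.8 ± 8.42 TPM in K700E, and the list test gave 0.715. With GC correction NBAS fell past the threshold (limma adjusted p 0.0476).

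Among cell cycle and checkpoint genes, named in the series title, a single gene passed in the planned test. The median changes of their lists lay from -0.14 (anaphase-promoting complex) to 0.07 (G1/S) log2 units relative to the median gene. CCND1, the cyclin D1 gene, rose from 7.59 ± 0.734 to 15.2 ± 1.94 TPM (SD, n = 3 each; log2 difference 0.91, SE 0.16, limma adjusted p 0.044). Leaving out any 1 library raised its limma adjusted p over 0.05, from 0.0659 without WT replicate 1 to 0.258 without WT replicate 3, while its log2 difference stayed between 0.84 and 1.01. Of 29 cyclins, kinases and inhibitors tested the other 28 did not pass, CDKN1A among them at 66.0 ± 10.5 and 100 ± 12.7 TPM (limma adjusted p 0.143). Adjusted over the list alone, 2 rose, and the list test gave an adjusted p of 0.831. None of 43 G1/S genes, 51 G2/M genes, 24 spindle checkpoint genes, 30 DNA damage and replication checkpoint genes or 19 anaphase-promoting complex genes passed, over all genes or adjusted over the list alone. RRM2, a subunit of ribonucleotide reductase, came nearest at 72.4 ± 7.18 and 119 ± 12.4 TPM (limma adjusted p 0.064). With GC correction RRM2 rose (limma adjusted p 0.0234), NASP (0.0261) and SPC25 (0.0489) fell, and CCND1 did not pass (0.106).

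As lists these cell cycle groups did not pass either. The camera adjusted p was 0.139 for G1/S, 0.0909 for G2/M, 0.266 for the spindle checkpoint, 0.752 for the DNA damage checkpoint and 0.440 for the anaphase-promoting complex. The G2/M list lay a median of -0.11 from all genes, with 37 of its 51 members below the median gene. It passed with median-ratio scaling (adjusted p 0.0227), TMM scaling (0.0187), protein-coding nuclear genes alone (0.0419) and GC correction (0.0149). Leaving out 1 library took the G2/M adjusted p from 4.53e-06 without WT replicate 2 to 0.609 without WT replicate 1, where its direction was upward, and it was 0.00920 without K700E replicate 1. The spindle checkpoint list passed without WT replicate 2 alone (0.00689), and the G1/S list passed, upward, without WT replicate 1 (0.00194) and with no filter on low values (0.0238).

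Erythroid and megakaryocytic genes, the lineages K562 cells can take, moved in single members rather than as lists. Of 27 globin and erythroid genes only the carbonic anhydrase genes CA1 and CA2 rose, CA1 from 8.72 ± 1.77 to 47.4 ± 15.6 TPM and CA2 from 1.85 ± 0.362 to 34.4 ± 26.4 TPM (SD, n = 3 each). The embryonic globin gene HBZ stood at 230.5 ± 62.6 and 492 ± 223 TPM and the transferrin receptor gene TFRC at 491 ± 33.3 and 839 ± 225 TPM, with limma adjusted p of 0.173 and 0.122. Of 27 heme and mitochondrial iron genes 26 did not pass. ALAS2, the first enzyme of heme synthesis in erythroid cells, was at 748 ± 28.2 and 1174 ± 197 TPM (limma adjusted p 0.092). Of 12 megakaryocyte genes ITGB3, an integrin of platelets, rose from 5.87 ± 0.287 to 22.2 ± 8.29 TPM, and the platelet chemokine gene PPBP fell from 2.68 ± 0.232 to 0.105 ± 0.0280 TPM. Adjusted over the list alone, 3 erythroid genes rose, 2 heme genes rose and 1 fell, and 4 megakaryocyte genes rose and 1 fell. The list tests gave adjusted p of 0.576, 0.510 and 0.373.

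Few markers of other lineages reached the level tested, and a single marker rose in each of the lymphoid and the stromal and epithelial lists. CD3D, a subunit of the T-cell receptor complex, was the only 1 of 4 lymphoid markers tested that rose, from 99.8 ± 2.88 to 289 ± 85.6 TPM (SD, n = 3 each), while the natural killer cell marker NKG7 was at 4.69 ± 2.17 and 3.49 ± 1.87 TPM. COL1A2 was the only 1 of 4 stromal and epithelial markers that rose, from 0.0423 ± 0.00724 to 3.84 ± 1.87 TPM, while EPCAM stood at 61.4 ± 17.8 and 56.6 ± 7.01 TPM and KRT19 at 146 ± 67.9 and 175 ± 34.9 TPM. Adjusted over the list alone, 2 lymphoid and 2 stromal markers rose, and the list tests gave 0.373 and 0.144. Myeloid genes were lower as a list (camera adjusted p 0.0025, median -0.51 from all genes), though none of the 9 tested passed singly, over all genes or adjusted over the list alone. The adjusted p of the myeloid list was 0.806 with an estimated correlation, 0.315 with no filter on low values, 0.119 with limma-voom on recovered reads, 0.0863 with a minimum of 5 TPM, 0.0547 without WT replicate 2 and 0.0600 without K700E replicate 1. The summed level of its 9 genes was 199, 289 and 237 TPM in WT and 152, 186 and 306 TPM in K700E, so K700E replicate 3 lay above every WT library. ITGAM stood at 9.24 ± 2.49 and 4.01 ± 4.12 TPM.

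Genes induced by NF-kB were higher as a list (camera adjusted p 0.0298, median 0.34 above all genes). Their adjusted p was 0.806 with an estimated correlation, 0.620 with a minimum of 5 TPM, 0.395 without WT replicate 1 and 0.114 without K700E replicate 3. CCL2, a chemokine for monocytes, rose from 0.311 ± 0.189 to 6.51 ± 3.21 TPM (SD, n = 3 each). IL6 rose from 1.995 ± 0.0757 to 5.06 ± 0.686 TPM, and TRAF1 and IL1B rose to 1.58 ± 0.153 and 1.99 ± 0.213 TPM, from WT means of 0.437 and 0.719 TPM. The other 12 of 16 members did not pass, and 4 rose when adjusted over the list alone.

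Immediate early, hypoxia and glycolysis genes included members that rose. SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, rose from 11.2 ± 0.675 to 34.2 ± 6.69 TPM and the zinc finger gene EGR2 from 0.330 ± 0.124 to 2.09 ± 0.665 TPM (SD, n = 3 each), 2 of 19 immediate early genes. EGR1 was at 49.8 ± 31.9 and 172 ± 5.88 TPM with a limma adjusted p of 0.090. NDRG1 rose from 16.9 ± 1.95 to 72.8 ± 39.8 TPM and ADM, which encodes the vasodilator adrenomedullin, from 1.02 ± 0.113 to 5.58 ± 1.07 TPM, 2 of 19 hypoxia genes. SLC2A3, a glucose transporter gene, rose from 234.6 ± 10.2 to 478 ± 64.1 TPM, 1 of 23 glycolysis genes. Adjusted over the list alone, 5 immediate early, 3 hypoxia and 1 glycolysis genes rose, and the list tests gave adjusted p of 0.0909, 0.179 and 0.179. The immediate early list passed without WT replicate 2 (0.00440), without WT replicate 3 (0.0452), with no filter on low values (0.00657) and with limma-voom on recovered reads (0.0380). The hypoxia list passed only with GC correction and no WT replicate 3 (0.0487).

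Histone genes whose transcripts mostly lack a poly(A) tail were higher as a list, with 13 of 14 above the median gene (camera adjusted p 0.00627). The adjusted p of the list was 0.806 with an estimated correlation, 0.155 without WT replicate 1 and 0.0944 without K700E replicate 2. H2BC4 rose from 19.3 ± 0.688 to 45.9 ± 9.47 TPM (SD, n = 3 each) and was the only 1 past the threshold over all genes, while 4 rose when adjusted over the list alone. H1-2 stood at 920.4 ± 319 and 1661 ± 79.2 TPM (limma adjusted p 0.134).

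Cytosolic ribosomal protein genes were lower in K700E as a list, with a camera adjusted p of 1.55e-24, and of 0.765 with an estimated correlation. All 40 lay below the median gene, at a median of -0.52 from it, and their summed level was 136300 TPM on average in WT and 102086 TPM in K700E. RPS23 stood at 1273 ± 47.4 and 915 ± 24.5 TPM, RPL4 at 3416 ± 310 and 2100 ± 462 TPM and RPS25 at 7727 ± 304 and 5751 ± 195 TPM (SD, n = 3 each), with limma adjusted p of 0.077, 0.113 and 0.096. None passed over all genes, and 10 fell when adjusted over the list alone. With GC correction 4 of the 40 fell over all genes. Ribosomal protein genes together took 19.5, 25.5 and 22.3% of TPM in the WT libraries and 16.7, 17.3 and 17.4% in the K700E libraries.

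Targets of the integrated stress response and of the unfolded protein response were lower as lists, with camera adjusted p of 0.00627 and 0.00756, each 0.765 with an estimated correlation. Their medians lay -0.21 from all genes in each case. The summed stress response genes stood at 3551, 4633 and 4210 TPM in WT and 3147, 3325 and 3612 TPM in K700E, and the unfolded protein response genes at 7565, 6430 and 6919 TPM in WT and 6638, 6613 and 7611 TPM in K700E, so the sums of both lists overlapped between the groups. PHGDH was the only 1 of 26 stress response genes that fell, over all genes and adjusted over the list alone. ATF5 stood at 515 ± 253 and 179.6 ± 90.2 TPM and ATF4 at 662 ± 59.3 and 572 ± 28.2 TPM (SD, n = 3 each), with limma adjusted p of 0.188 and 0.428. None of 20 unfolded protein response genes passed, over all genes or adjusted over the list alone, DNAJC3 being at 23.8 ± 4.43 and 14.4 ± 1.00 TPM, and the list's adjusted p was 0.0713 without K700E replicate 2. With GC correction 2 of these 20 genes fell over all genes. PHGDH also belonged to the serine and one-carbon list, where it was the only 1 of 16 that fell over all genes and over the list alone (list adjusted p 0.373).

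The remaining lists had no member past the threshold over all genes and did not pass as lists in the planned test. The camera adjusted p was 0.191 for 26 MYC targets, 0.993 for 14 interferon-stimulated genes, 0.752 for 17 p53 targets and 0.373 for 21 apoptosis regulators. It was 0.373 for 37 nuclear respiratory chain genes, 0.576 for 13 mitochondrial transcripts and 0.0909 for 24 cholesterol synthesis genes, which passed, upward, without WT replicate 1 (0.0119), WT replicate 3 (0.0177) or K700E replicate 1 (0.0212), and with no filter on low values (0.0265). MYC stood at 97.8 ± 14.1 and 127 ± 10.6 TPM, and TNFRSF10B, a death receptor gene among the p53 targets, at 82.8 ± 16.4 and 156 ± 31.3 TPM (SD, n = 3 each), with limma adjusted p of 0.270 and 0.089. K562 cells lack functional p53, so the p53 list is no readout of p53 activity in them. Adjusted over the list alone, 1 interferon-stimulated gene rose and 1 fell, 1 p53 target rose, and no gene of the other 5 lists passed.

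**Figure D2:**
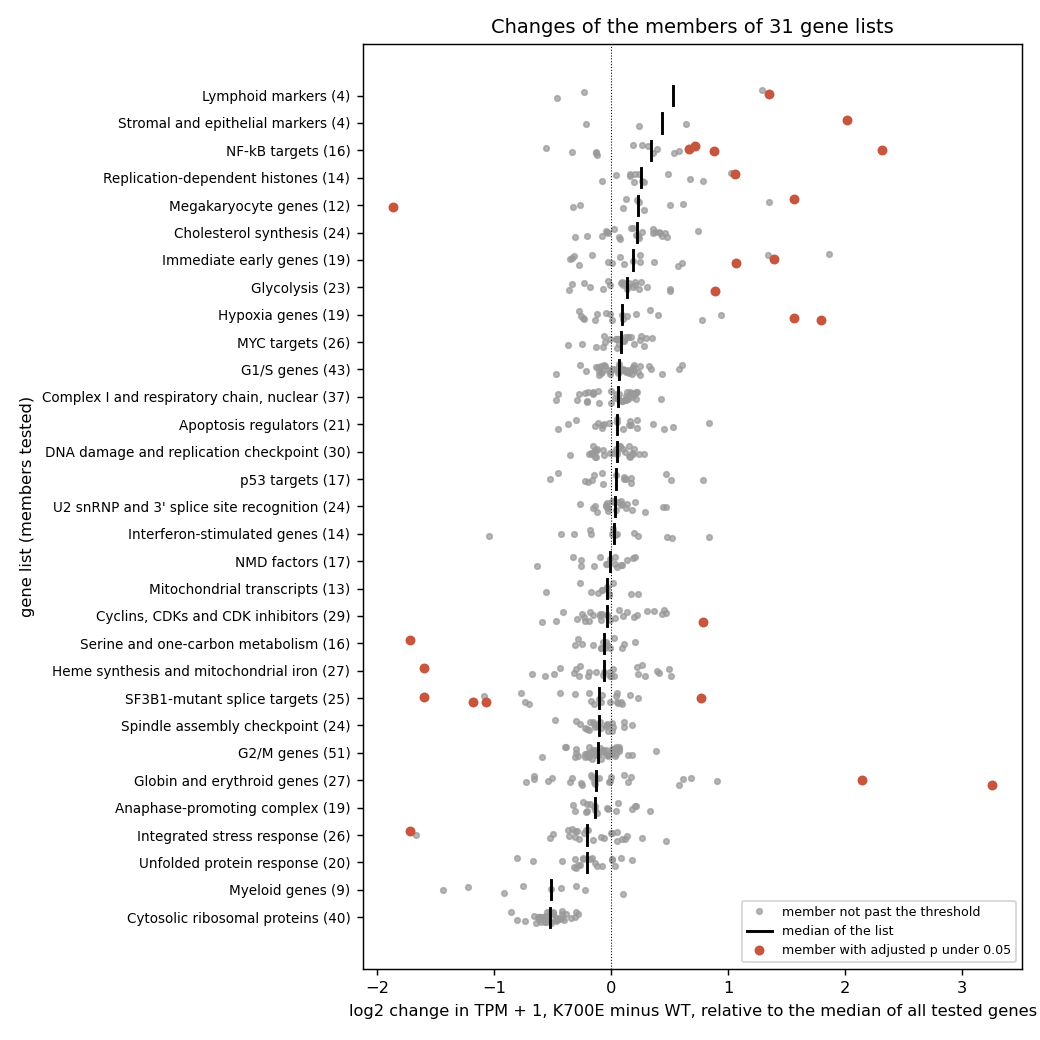
Log2 change in TPM + 1 of each tested member of 31 gene lists, K700E minus WT, relative to the median of all 15493 tested genes; each point is a gene, filled in red at an adjusted p under 0.05, and black bars are list medians. The 40 cytosolic ribosomal protein genes lie left of 0 without a member past the threshold, and CA2 and CA1 lie far right among the erythroid genes.

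The libraries differed within groups along GC content, and the WT group more than the K700E group. Across 5928 genes of at least 20 TPM, the rank correlation of the log2 ratio with GC content was -0.79 between WT replicates 1 and 2 and -0.55 between K700E replicates 1 and 3. These correlations are across genes, which are not independent replicates. For the difference between the group means it was -0.01. With the trend on GC content removed from each library, a step chosen after the data were seen, 290 genes were higher and 212 lower, among them 186 of the 214, and 0 were called without WT replicate 3 (1963 unadjusted). The correction also centred each library, which moved the median log2 difference from 0.13 to 0.003. Median-ratio scaling, which centres without GC content, gave 119 higher and 41 lower genes. The effects of centring and of GC content were not separated within the correction.

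**Figure D3:**
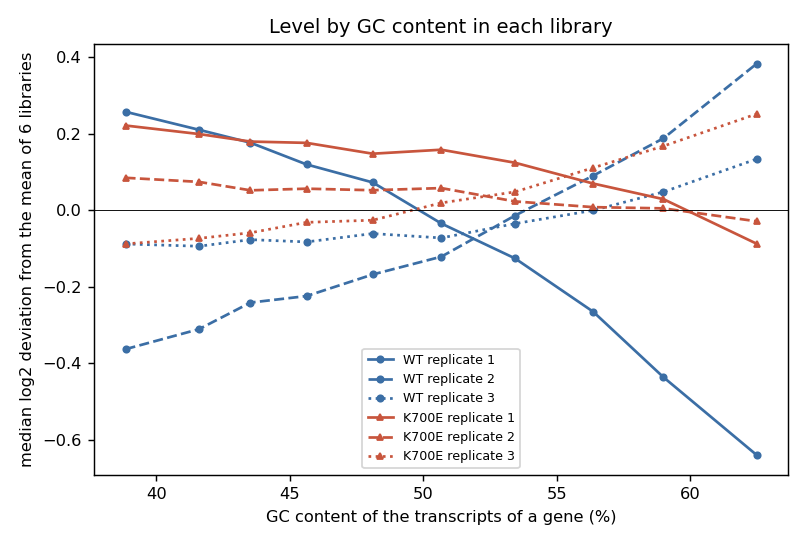
Median log2 deviation of each library from the mean of the 6 libraries, in 10 bins of 5928 genes by the GC content of their transcripts in percent (blue circles, WT; red triangles, K700E). WT replicate 1 runs from 0.26 in the lowest bin to -0.64 in the highest, and WT replicate 2 from -0.36 to 0.38.

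WT replicate 3 lay between WT replicates 1 and 2 in most genes. Of 11104 genes with a mean of at least 500 reads, 82.9% had the WT replicate 3 value between the other two WT values, where chance gives 33.3%. For K700E replicates 1, 2 and 3 the share between the other two was 25.3, 48.8 and 25.9%. The SD of the log2 ratio between WT replicates 1 and 2 was 0.73, and that between WT replicate 3 and a weighted sum with 42.5% of WT replicate 1 and 57.5% of WT replicate 2 was 0.11. The calls given above therefore rest on a WT spread that includes this library.

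**Figure D4:**
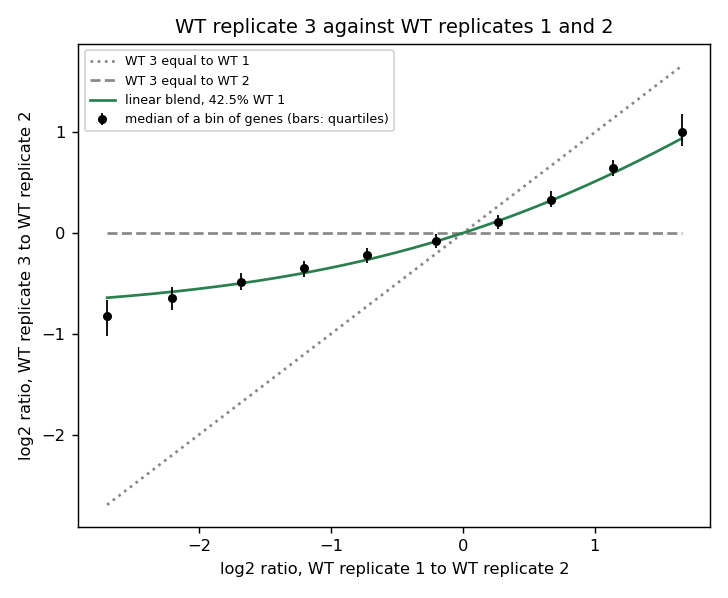
Log2 ratio of WT replicate 3 to WT replicate 2 against that of WT replicate 1 to WT replicate 2, as medians and quartiles over bins of genes with a mean of at least 500 reads. Lines show equality with either library and a weighted sum with 42.5% of WT replicate 1. The medians run from -0.82 where WT replicate 1 is lowest to 1.00 where it is highest and lie near the weighted sum.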

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

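The GC correction, the fits on recovered reads and their combinations were chosen after the data were seen; all other settings were planned. SF3B1 stayed below the threshold in all 20 alternatives. Higher and lower genes numbered 0 and 0 with no filter on low values (4891 at an unadjusted p under 0.05 by limma), 73 and 19 with a mean of at least 5 TPM, 110 and 41 with TMM factors, 290 and 212 with GC correction, and 309 and 72 with limma-voom on recovered reads. Leaving out 1 library gave 0 to 144 higher and 0 to 38 lower genes, and 0 and 0 again without WT replicate 3 after GC correction (1963 unadjusted) or with limma-voom (2415 unadjusted). The cause of these moves was not tested, except that the 5 TPM filter tests fewer genes (10577) and leaving out a library leaves fewer libraries. Of the lists, 5 to 10 passed in the other settings and 0 with the correlation estimated.

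Same-numbered libraries deviated from their group means with correlations of 0.28, -0.19 and 0.30, and of 0.12, -0.12 and 0.09 after GC correction. WT replicate 2 and K700E replicate 3, with unlike numbers, reached 0.43 before that correction. With 3 libraries per group these values neither show nor exclude a pairing by number. With the replicate block 59 genes were higher and 8 lower, and with GC correction and the replicate block 55 and 28. Of the 7 lists called, the block ended the call of the NF-kB list (adjusted p 0.0605) and no other, and with GC correction the cholesterol synthesis (0.0493) and G2/M (0.00845) lists passed under it.

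Among named genes without a call, the log2 change reversed for BIRC5 with median-ratio (-0.002322) and TMM (-0.01344) factors and for MT-ND3 with TMM factors (-0.00739). Without 1 library KRT19 ranged from -0.06405 (WT replicate 1) to 0.6807, and EPCAM from -0.3071 to 0.1167 (WT replicate 1), with 0.01987 without K700E replicate 1; the cause was not tested.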

Other observations

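The genes in the opening paragraphs were chosen after their values were seen, as were the tests on GC content, WT replicate 2, paired genes, chance placement and other splits. Among the called genes outside the lists, PROCR, the endothelial protein C receptor gene, rose from 12.6 ± 1.51 to 48.0 ± 14.4 TPM (SD, n = 3 each), PLAT, tissue plasminogen activator, from 0.639 ± 0.149 to 2.70 ± 0.127 TPM, and LOXL2, a lysyl oxidase, from 2.77 ± 0.447 to 10.97 ± 0.940 TPM. These genes were picked one by one and no group was tested.

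On the X chromosome SSX1 rose from 29.1 ± 0.989 to 76.7 ± 20.6 TPM, MAGEC2 from 119.5 ± 7.11 to 205 ± 14.3 TPM, MAGEC1 from 83.6 ± 1.45 to 127.9 ± 0.247 TPM and SAGE1 from 18.3 ± 2.28 to 38.1 ± 5.55 TPM (SD, n = 3 each), while PAGE5 fell from 10.995 ± 1.085 to 1.55 ± 1.36 TPM. SSX and MAGE genes have near-identical copies, so the split of reads between them is uncertain. They were likewise picked one by one, and the family was not tested.

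Genes higher in K700E lay near each other more often than random genes did, since 35 of 178 had another higher gene within 250 kb, where 10000 random sets matched on level had a median of 16 and 97.5% of them at most 27 (permutation p = 0.001), which argues against chance placement, and 5.71% of the 35 overlapped another in position, which argues against reads shared by overlapping genes as the whole account. Reads shared between similar copies, such as SSX1 and SSX6P, SLC2A3 and SLC2A14, or the T-cell receptor segments, were not tested and stay open. On chromosome 7, between 142419212 and 142583490 (GRCh37), lay the T-cell receptor beta segments TRBV27, TRBV28 and TRBD1 with EPHB6 and TRPV6, and on chromosome 8, between 86239837 and 86393722, CA1, CA3 and CA2. CA3 rose from 0.857 ± 0.114 to 7.29 ± 3.39 TPM and TRBV27 from 1.76 ± 1.30 to 12.7 ± 4.29 TPM (SD, n = 3 each), and TRBD1 was listed at 0 in all 3 WT libraries. A short segment can pass 1 TPM on few reads, so the call of TRBD1 may rest on few. Regional change of chromatin or copy number in the K700E cells is a candidate explanation that was not tested, as is a difference between clones that has nothing to do with the substitution.

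WT replicate 3 may be a blend of WT replicates 1 and 2. In 161 genes at least 4-fold apart between those libraries, the residual of a linear blend was 0.572 times that of a blend on the log scale. A linear blend needs the same share of WT replicate 1 on both sides, and genes at least 2-fold lower and higher there gave 42.1 and 47.4%, against 29.2 and 59.7% on the log scale. The linear share fitted in the 161 genes was 0.496, against 0.425 over all 11104 genes, so the need for a single share was met only roughly. GC bias alone is argued against, since 76.6% of genes still had WT replicate 3 in between after GC correction (25.7 to 40.2% for the K700E libraries). The median squared residual was 2.29 times the counting variance of fragments, where counting alone gives 0.455. Over these 11104 genes this argues against a plain mix of the reads of WT replicates 1 and 2, which would leave only counting error. Whether cells or RNA were mixed, or the cultures differed in this way by themselves, stays open. No biological explanation was tested.

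The median log2 change of ribosomal protein genes, -0.524 relative to all genes, stayed at -0.531 after GC correction, which also centred the libraries. Relative to all genes it was -0.376 without WT replicate 2, the library with the highest share of these transcripts. A loss of short abundant transcripts stays open. Only 24 of the 40 genes had another protein-coding gene within 0.5 log2 units of their length and level. Those partners lay a mean of 0.385 above them (SE 0.07 over pairs, which are not independent replicates), higher in 22 of 24 pairs. The bounds of this test were set after a trial of the pairing. Too few genes had a partner, and the mean difference less 2 standard errors also fell short of its bound. Length here covered all annotated exons of a gene, not its transcripts, with a median of 2144.5 bases for the paired ribosomal protein genes. The pairs therefore cannot show what happened to short transcripts. The pairs replaced an earlier test, with bounds set beforehand, in which the 61 nearest genes lay 0.434 above the ribosomal protein genes, past its bound, but were longer (median 2339 against 1279 bases) and less abundant (1076 against 2159 TPM), so that it did not compare like with like. Of 22 genes of translation factors and related proteins, also chosen after the result was seen, 18 lay below the median gene, at a median of -0.39 from it. The genotype stays open as an untested explanation, as do growth state at harvest and a difference in aligner or library batch between the tables.

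With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 214 genes and was the only 1 of the 10 to reach that count, the highest other being 0. The splits are not alike, since only the real one keeps WT replicate 3 with both libraries that it may blend. Without WT replicate 3 the real contrast also called 0 genes. For lists 3 of the 10 splits reached the real count of 7, the highest other being 16, from WT replicates 1 and 3 with K700E replicate 3 against the rest. The split of WT replicate 1 with K700E replicates 1 and 2 against the rest, which follows the GC gradient, gave 3261 genes at an unadjusted p under 0.05 against 2563 for the real split. On chromosome 15 the median gene lay -0.17 from all tested genes, with 76.7% of its 498 genes below the median gene, and chromosome 14 followed at -0.07.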
